A study of Mus musculus with 23 samples.

How the data were processed

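Small RNA libraries of 6 mouse cell populations were measured, 23 libraries in all: 4 each of lung ILC2, IL-33 ILC2, cultured ILC2, CD4 T cells and cultured Th2, and 3 of OVA-lung Th2. Per the labels, lung ILC2 were sorted as CD45+ Thy1+ lineage-negative CD4- CD25+ ST2+ cells of wild-type mice, IL-33 ILC2 in the same way after 500 ng of IL-33, and cultured ILC2 were kept with 10 ng/ml of each cytokine. CD4 T cells were sorted as CD4+ CD62L-high CD44-low CD25- CD69- cells. OVA-lung Th2 were reporter-positive CD4+ CD3+ cells after sensitization with 50 µg of ovalbumin and challenge over 3 days, and cultured Th2 were grown with 500 U/ml of IL-4 and 10 µg/ml of antibody to interferon gamma.

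The deposited count tables hold expected counts per mature or precursor microRNA, which need not be whole (9.98% of the values above 0 are fractional). There are 4 such tables with 871, 1141, 482 and 725 entries, 1256 in the union and 417 in all 4. A microRNA absent from a table was set to 0 there. The deposited normalized table holds RPM, reads scaled to a column sum of 1000000, for 1099 entries, and 100% of its 7929 values above 0 are whole multiples of 1 read within a tolerance of 0.01. The reads so recovered equal the rounded counts within 1 read in 100% of cases, so no scaling beyond the column total is visible in them. Per the submitters' processing notes the build is mm10 and DESeq2 was used, with no version. The aligner, the version of the counting software, the trimming and the annotation are not given in the sources used here. Of the columns of values 46 were used and 6 were not, the authors' group averages in the RPM table, and 1 empty line was dropped. The 56 precursor entries, 0.00108% of the counts, were kept.

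Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group with its defaults, which left 384 microRNAs, 1 fit of all 6 groups, and quasi-likelihood F-tests with robust estimation under the default method of this version. P-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p below 0.05 is a call. The comparisons were 7 pairs of groups and 2 tests of whether the change on activation differs between the lineages, in vivo and in culture. TMM factors ran from 0.20 in cultured Th2 library 4, in which miR-21a-5p held 82.23% of the counts, to 3.10 in lung ILC2 library 3. The choice of scaling moves the whole set of fold changes. With the block, the medians of all log2 changes under TMM, DESeq2 size factors and library totals were −1.09, −0.33 and −0.19 for lung ILC2 against CD4 T cells, 0.78, 0.09 and −0.14 for cultured and 0.66, −0.01 and −0.20 for IL-33 against lung ILC2. They were −0.58, 0.10 and −0.45 for OVA-lung Th2 and 0.36, 0.66 and −0.30 for cultured Th2 against CD4 T cells, 0.04, −0.52 and 0.09 for IL-33 ILC2 against OVA-lung Th2, and −0.51, −0.86 and −0.02 for the cultured pair.

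Fixed before the data were examined were the comparisons, the test without a block, the fit with the replicate number as a block as its alternative, the microRNA lists and the rule for named microRNAs. Per the labels each replicate number belongs to 1 count table, taken here as a shared batch that pairs the libraries of a number. Whether they deviate together was checked over the 204 microRNAs with at least 10 counts in at least 12 libraries. Deviations from the group means correlated above 0.1 in 51 of 55 pairs with the same number (lowest −0.03, median 0.39, highest 0.77), against a median of −0.15 between numbers (−0.55 to 0.29). Of the 23 libraries 22 correlated best with their own number. The block lowered the biological coefficient of variation from 1.54 to 1.13. There is no OVA-lung Th2 library in the fourth table.

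Named microRNAs follow a rule. In each pair of groups it takes the 10 largest and 10 smallest log2 changes among calls with a mean log2 CPM of at least 6 and no overlap between the libraries of the groups, and for the differences between lineages 5 and 5. It adds up to 4 members of each list with at least 3 tested members, those with the smallest p, every member of the miR-17-92 cluster with a mean log2 CPM of at least 6, the 5 most abundant of each population, miR-155, miR-21a, miR-146a and miR-150, and markers of other cells. After the data were seen, the rule was also applied to the calls with the block, with the same direction in every count table in place of no overlap. Lists were the miR-17-92 cluster and its paralog clusters, the let-7, miR-15-16, miR-29, miR-30 and miR-181 families, the clusters of miR-23, miR-27 and miR-24, microRNAs known to rise in activated T cells or to be high in resting lymphocytes, the Dlk1-Dio3 and Sfmbt2 loci, and markers of myeloid, endothelial, epithelial, mesenchymal and erythroid cells and of liver or muscle. Entries were assigned to lists by the number in their name. So the miR-17-92 list holds miR-92a-2-5p, and miR-19b-3p, which also has a copy on chromosome X. Of the 36 Sfmbt2 entries 34 were placed at the locus and the others were not placed. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, adjusted over all lists and pairs of groups. Members were also adjusted over the list alone.

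Other tests were DESeq2 1.42.0 (Wald test) and limma on log2(RPM + 1). These and the following alternatives were fixed beforehand: DESeq2 size factors, library totals, no filter, fits of only the groups compared, only microRNAs in all 4 tables, the block with TMM and with DESeq2 size factors, and each library left out. Added after seeing the data were the newer quasi-likelihood method and, with the block, library totals, the DESeq2 test, the newer method, a filter of 10 counts in 12 libraries, fits of only the groups compared, each library left out, and the fit without the 3 libraries under 100000 counts. Detection floors are 3 counts and cover counting error only. Recovery was tested on simulated counts with 200 changed microRNAs in each of 5 draws. Of the 384 microRNAs 374 were placed on GRCm38. Entries that share sequence, such as the Sfmbt2 members, miR-486a and miR-486b, and miR-199a and miR-199b, cannot be told apart with certainty, and 15 tested entries have the same counts as another. Within the groups, no library was a copy of another. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.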

Results

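MicroRNAs were profiled by small RNA sequencing in 23 mouse libraries from 6 cell populations, in a study of microRNA control of group 2 innate lymphoid cells (ILC2) and T helper 2 (Th2) cells in allergic inflammation of the lung. The ILC2 groups were lung ILC2 from untreated wild-type mice (n = 4) and lung ILC2 taken after 3 days of IL-33 given by oropharyngeal aspiration (IL-33 ILC2, 500 ng, n = 4). Further ILC2 were kept for 10 days in culture with IL-33, TSLP and IL-7 (cultured ILC2, n = 4). The T cell groups were CD62L-high, CD44-low CD4 T cells of spleen and lymph node (CD4 T cells, n = 4) and lung CD4 T cells carrying the Il4 reporter after ovalbumin sensitization and challenge (OVA-lung Th2, n = 3). Th2 cells were also made in culture over 5 days (cultured Th2, n = 4). Library totals ran from 84918 to 28371920 counts, with a median of 832220. In every comparison 384 mature microRNAs were tested. The libraries come from 4 count tables that hold 1 library per group. The replicate number names the table. Values are therefore given from the fit with the replicate number as a block, as log2 differences with standard errors. The count of calls without the block stands beside each comparison. CPM (counts scaled to a library total of 1000000) and shares are means with SD over the libraries of a group. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

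The 6 populations differed first in how much of their microRNA was miR-21a-5p, a microRNA known to be induced by activation of lymphocytes. It held 5.04 ± 3.99% of the counts in lung ILC2, 20.4 ± 19.3% in IL-33 ILC2, 33 ± 24% in cultured ILC2, 44.4 ± 11.5% in OVA-lung Th2 and 50 ± 23.4% in cultured Th2. In lung ILC2 the most abundant microRNAs were let-7i-5p (9.17 ± 7.54%), let-7f-5p (8.32 ± 5.01%), miR-24-3p (6.74 ± 6.91%), let-7a-5p (5.7 ± 1.04%) and miR-21a-5p. In CD4 T cells they were let-7f-5p (10.7 ± 5.8%), miR-29a-3p (6.46 ± 4.2%), let-7g-5p (5.59 ± 1.88%), miR-150-5p (5.43 ± 5.02%) and let-7i-5p (5.38 ± 4.51%). After miR-21a-5p, IL-33 ILC2 held most of miR-24-3p (8.14 ± 9.51%), let-7i-5p (7.84 ± 5.66%), let-7f-5p (6.34 ± 3.65%) and let-7c-5p (4.25 ± 3.37%). Cultured ILC2 held most of let-7i-5p (12.8 ± 14.6%), let-7f-5p (6.77 ± 0.704%), miR-146a-5p (3.71 ± 1.85%) and let-7a-5p (3.69 ± 1.37%). In OVA-lung Th2 the next were miR-24-3p (3.75 ± 4.55%), miR-142a-5p (3.4 ± 2.02%), let-7f-5p (3.35 ± 0.985%) and let-7i-5p (2.97 ± 0.975%). In cultured Th2 they were miR-24-3p (4.63 ± 7.34%), let-7f-5p (4.39 ± 1.9%), let-7i-5p (3.95 ± 3.27%) and miR-29a-3p (2.56 ± 1.67%). The 20 tested microRNAs fixed as known to rise in activated T cells made up, with 4 untested entries, 7.33 ± 3.25% of the counts of lung ILC2 and 5.14 ± 3.17% of CD4 T cells. The share was 24.6 ± 16.3% in IL-33 ILC2, 38.2 ± 22.1% in cultured ILC2, 47.1 ± 10.9% in OVA-lung Th2 and 51.3 ± 23.6% in cultured Th2.

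Lung ILC2 and CD4 T cells, both taken without stimulation, differed in miR-150-5p, a regulator of Myb known from mature resting lymphocytes. It was lower in ILC2 by −5.67 ± 0.64 log2 (adjusted p = 1.65e-08), at 1850 ± 1790 CPM in lung ILC2 (n = 4) against 54300 ± 50200 CPM in CD4 T cells (n = 4). Its other arm miR-150-3p differed by −6.07 ± 1.09. miR-181a-5p, which tunes T cell receptor signaling during thymic development, was lower by −3.97 ± 0.67 (adjusted p = 3.79e-05). miR-142a-5p, of the blood cell locus Mir142, differed by −2.69 ± 0.53 (adjusted p = 0.000444). Higher in ILC2 were miR-146b-5p, a relative of the NF-kB feedback microRNA miR-146a (5.81 ± 0.75, 12000 ± 6000 against 174 ± 255 CPM), and miR-23a-3p (4.40 ± 0.65, 1.78 ± 1.29% against 0.0543 ± 0.0526% of the counts). So were miR-27a-3p (3.68 ± 0.66), miR-24-3p (1.90 ± 0.42) and miR-99b-5p (2.59 ± 0.58). Higher too was miR-126a-3p, known as a microRNA of endothelial cells (8.71 ± 1.24, 0.783 ± 0.857% against 0.000862 ± 0.00137% of the counts). Each of these 10 microRNAs was on the same side in 4 of 4 count tables, and the call held with each library left out and under both other scalings.

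By list, the microRNAs of the Sfmbt2 locus, an intron of the imprinted Polycomb gene Sfmbt2 that holds many near-identical hairpins, stood furthest below the CD4 T cells in lung ILC2. Of 36 tested members 14 were lower, 21 adjusted over the list alone, and all 36 lay below 0 (median −4.83). Only these 36 of the 111 entries of the list passed the filter, which entries high in CD4 T cells pass more readily. All 111 entries made up 1.32 ± 0.875% of the counts of CD4 T cells and 0.116 ± 0.119% of lung ILC2. Examples are miR-669c-5p (−4.87 ± 1.23), miR-467a-5p (−5.42 ± 1.37) and miR-467b-5p (−5.35 ± 1.38). The list test gave an adjusted p of 2.69e-11 with the preset correlation and adjusted p = 0.0494 with an estimated correlation. The near-identical sequences leave the assignment to single members uncertain, and the 36 entries hold 30 distinct count profiles. Of the clusters of miR-23, miR-27 and miR-24, 6 of 12 members were higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.0023, then adjusted p = 0.114 with an estimated correlation). Of the microRNAs known to be high in resting lymphocytes, 4 of 12 were lower (6 adjusted over the list alone, adjusted p = 0.0203, then adjusted p = 0.348 with an estimated correlation). Of the miR-181 family 2 of 6 were lower (3 adjusted over the list alone, adjusted p = 0.0269, then adjusted p = 0.38 with an estimated correlation).

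The list of the proliferation-associated miR-17-92 cluster had 3 of 12 entries lower in lung ILC2 than in CD4 T cells (3 adjusted over the list alone). They were miR-17-5p (−2.30 ± 0.62), miR-92a-3p (−1.84 ± 0.49) and miR-92a-2-5p, which by its name comes from a second copy outside the cluster and had 0 counts in all 4 lung ILC2 libraries. The calls of miR-17-5p and miR-92a-3p were lost under both other scalings, and that of miR-17-5p also without lung ILC2 library 3 or 4 (−2.92 to −1.93). Its paralog clusters had 3 of 11 lower (6 adjusted over the list alone, adjusted p = 0.0305, then adjusted p = 0.439 with an estimated correlation). The miR-15-16 family had 2 of 10 lower (4 adjusted over the list alone), the miR-29 family 1 of 5 (1 adjusted over the list alone), and the miR-30 family 0 of 11. In the let-7 family 1 of 16 was higher and 2 lower, and its median turned with the scaling, from −0.81 to 0.01 with size factors and 0.27 with library totals. Of the microRNAs known to rise in activated T cells, 2 of 20 were higher, with a median of −0.83 that was 0.01 with library totals. Markers of other cells differed as well. The erythroid list had 0 of 6 members higher (5 adjusted over the list alone, adjusted p = 0.0102, then adjusted p = 0.38 with an estimated correlation). The mesenchymal list had 1 of 8 (3 adjusted over the list alone, adjusted p = 0.0026, then adjusted p = 0.298 with an estimated correlation), which was miR-143-3p of smooth muscle and fibroblasts (7.03 ± 2.13, 6130 ± 2770 against 46.2 ± 52.2 CPM). That call was lost under both other scalings and without lung ILC2 library 1, 3 or 4 or any 1 CD4 library (6.34 to 7.63). The Dlk1-Dio3 list had 1 of 17 higher (1 adjusted over the list alone, adjusted p = 0.0293, then adjusted p = 0.753 with an estimated correlation). Its sum was higher in the 3 count tables in which either library had counts.

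In all, 14 microRNAs were higher and 34 lower in lung ILC2 than in CD4 T cells with the replicate block (14 and 11 with size factors, 16 and 10 with library totals). Without the block 3 were higher and 3 lower: miR-126a-3p (8.86), miR-146b-5p (4.96), miR-23a-3p (4.19), miR-150-5p (−5.76), miR-150-3p (−5.79) and miR-181a-5p (−3.87). The blocked count of 48 became 26 (10 and 16) without lung ILC2 library 3 and 25 (13 and 12) without lung ILC2 library 4. The ILC2 came from lung and the T cells from spleen and lymph node, so lineage and tissue cannot be told apart in this comparison.

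After 10 days in culture with IL-33, TSLP and IL-7, ILC2 held more miR-21a-5p (3.78 ± 0.48 log2, adjusted p = 5.59e-07, 330000 ± 240000 CPM, n = 4, against 50400 ± 39900 CPM, n = 4). They also held more miR-146a-5p, which restrains NF-kB signaling through Traf6 and Irak1 (3.42 ± 0.55, adjusted p = 4.37e-05, 37100 ± 18500 against 8020 ± 3870 CPM). Both rose in 4 of 4 count tables and kept the call with each library left out. With them 4 of the 20 microRNAs known to rise in activated T cells were higher, 10 adjusted over the list alone (adjusted p = 0.000828, then adjusted p = 0.11 with an estimated correlation). The others were miR-21a-3p (3.64 ± 1.01) and miR-155-5p, which is needed for full Th2 and ILC2 responses (5.02 ± 1.41, adjusted p = 0.0439, 6070 ± 9490 against 427 ± 488 CPM, higher in 3 of 4 count tables). The call of miR-21a-3p was lost without lung ILC2 library 2, 3 or 4 or cultured ILC2 library 2 or 4 (3.31 to 4.60). That of miR-155-5p was lost without lung ILC2 library 2, 3 or 4 or cultured ILC2 library 2, 3 or 4 (4.48 to 6.03). Both were lost under both other scalings. Of the microRNAs known to be high in resting lymphocytes 2 of 12 fell, 3 adjusted over the list alone (adjusted p = 1.68e-05, then adjusted p = 0.0683 with an estimated correlation). Among these miR-150-5p fell from 1850 ± 1790 to 267 ± 264 CPM (−2.09 ± 0.56, adjusted p = 0.0252), a call lost without lung ILC2 library 1 or 2 or cultured ILC2 library 1, 2 or 4 (−2.50 to −1.53).

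The other group that rose in cultured ILC2 was the imprinted Dlk1-Dio3 locus on chromosome 12, a maternally expressed cluster known from embryonic and stem cells. Of its 17 tested members 6 rose (12 adjusted over the list alone with the block, 14 without) and all 17 lay above 0. Only these 17 of the 74 entries of the list passed the filter, which entries high in cultured ILC2 pass more readily. For example, miR-410-3p, miR-431-5p and miR-666-5p had 0 counts in lung ILC2, IL-33 ILC2 and CD4 T cells. The member counts, the median and the list test therefore lean towards a rise. The median was 7.65, or 5.61 with members at 0 counts in 1 group set at a floor of 3 counts. The sum over all 74 entries, tested or not, was higher in 4 of 4 count tables (mean 4.04, SD 1.63 log2). It took 0.283 ± 0.346% of the counts against 0.0131 ± 0.0133% in lung ILC2. The list test gave an adjusted p of 7.92e-08 and adjusted p = 0.311 with an estimated correlation. Examples are miR-541-5p (adjusted p = 0.00903, 304 ± 302 against 5.66 ± 11.3 CPM), whose call was lost without lung ILC2 library 4 or cultured ILC2 library 1, and miR-409-3p (adjusted p = 0.0252, 300 ± 437 against 1.59 ± 3.19 CPM), lost without lung ILC2 library 2 or 4 or cultured ILC2 library 3 or 4. Both had counts in 1 of 4 lung ILC2 libraries, so no size is given. The miR-17-92 cluster had 0 of 12 members past the threshold over all microRNAs and 7 higher adjusted over the list alone (adjusted p = 0.0241, then adjusted p = 0.256 with an estimated correlation). Its summed share did not rise, at 3.75 ± 2.5% of the counts against 3.84 ± 2.25% in lung ILC2. That sum was mostly miR-92a-3p, at 28000 ± 25700 CPM in cultured and 32900 ± 24600 CPM in lung ILC2. Of the 12 members 11 lay above 0 and 1 below, with a list median of 2.02. The median of all changes here was 0.78 under TMM and −0.14 with library totals. In the let-7 family miR-98-5p rose (3.01 ± 0.68, adjusted p = 0.00903, lost without lung ILC2 library 4, 2.64 to 3.58). The family median turned from 0.46 to −0.28 with size factors and −0.58 with library totals.

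Endothelial miR-126a-3p fell in culture (−3.96 ± 1.01, adjusted p = 0.0252, 0.0199 ± 0.0178% against 0.783 ± 0.857% of the counts). That call was lost without lung ILC2 library 2 or cultured ILC2 library 1, 2 or 4 (−4.47 to −3.35). The mesenchymal list had 0 of 8 members past the threshold (adjusted p = 0.0269, lower, then adjusted p = 0.439 with an estimated correlation), at 0.0565 ± 0.0764% against 0.68 ± 0.339% of the counts. In all 14 microRNAs rose and 3 fell with the block (7 and 9 with size factors, 5 and 10 with library totals). Without it 1 rose and 0 fell, miR-21a-5p (4.05, adjusted p = 0.0444). The blocked count of 17 was 5, 9 and 4 (2 and 2) without lung ILC2 libraries 2, 3 and 4, and 10, 11 and 4 without cultured ILC2 libraries 2, 3 and 4.

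At 3 days after IL-33 reached the airways, lung ILC2 held 204000 ± 193000 CPM of miR-21a-5p (n = 4) against 50400 ± 39900 CPM in untreated mice (n = 4). It was higher in 4 of 4 count tables (2.68 ± 0.47 log2, adjusted p = 0.000505 with the block and 0.436 without). miR-146a-5p stood at 25900 ± 28400 against 8020 ± 3870 CPM, also higher in 4 of 4 tables (2.26 ± 0.54, adjusted p = 0.0263 with the block and 0.631 without). These were the only calls with the block, 2 higher and 0 lower, and both belong to the 20 microRNAs known to rise in activated T cells (2 adjusted over the list alone, adjusted p = 0.0192, then adjusted p = 0.256 with an estimated correlation). miR-155-5p did not pass (2.85 ± 1.31, adjusted p = 0.591, 1360 ± 1680 against 427 ± 488 CPM). The miR-17-92 cluster had 0 of 12 members past the threshold and 1 lower adjusted over the list alone (adjusted p = 0.00869, lower, then adjusted p = 0.148 with an estimated correlation). The Dlk1-Dio3 list had 0 of 17 past the threshold (adjusted p = 0.0775). Its sum was lower in the 3 count tables in which either library had counts.

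Without the block edgeR called 0 microRNAs between IL-33 ILC2 and lung ILC2, with 22 at an unadjusted p below 0.05. DESeq2 called 1 higher and 2 lower and limma on the deposited RPM called 0. The call of miR-21a-5p was lost without lung ILC2 library 2 or IL-33 ILC2 library 4 (2.17 to 3.14). That of miR-146a-5p was lost without any 1 lung ILC2 library or IL-33 ILC2 library 1 or 4 (1.62 to 2.62) and under both other scalings (1.29 to 1.57). The blocked count was 0 without lung ILC2 library 2 or IL-33 ILC2 library 4, 1 without lung ILC2 library 3 or 4 or IL-33 ILC2 library 1, and 3 without lung ILC2 library 1. With as few calls, 2 of 35 splits of these 8 libraries gave as many or more, so chance cannot be excluded.

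**Figure D1:**
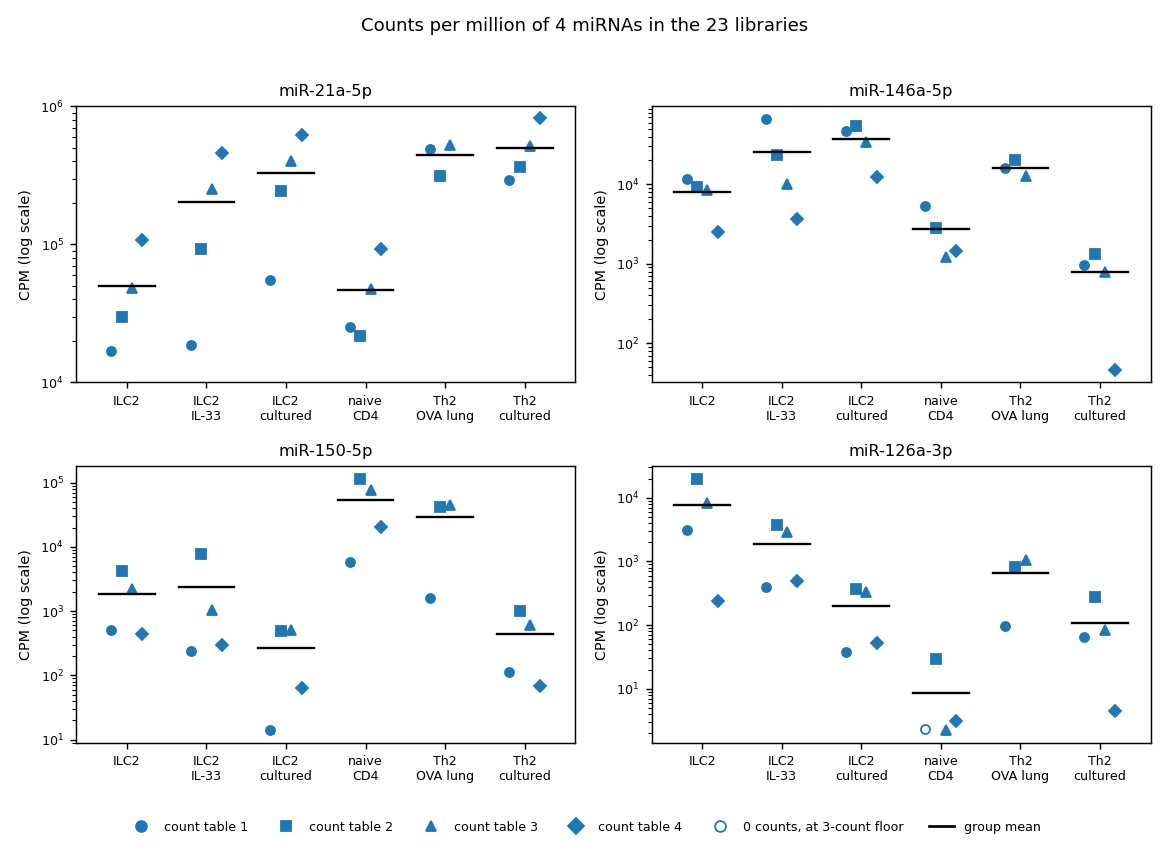
CPM of miR-21a-5p, miR-146a-5p, miR-150-5p and miR-126a-3p in each of the 23 libraries on a log axis, by group. Marker shape gives the count table, the line the group mean, and open symbols are libraries at 0 counts drawn at a floor of 3 counts. In the blocked fit miR-21a-5p was higher in each stimulated group than in its resting control, and in IL-33 ILC2 that call was lost without lung ILC2 library 2 or IL-33 ILC2 library 4.

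In the T cell lineage, lung Th2 cells of ovalbumin-challenged mice held 444000 ± 115000 CPM of miR-21a-5p (n = 3) against 46800 ± 32600 CPM in CD4 T cells (n = 4), a rise of 3.94 ± 0.50 log2 (adjusted p = 5.58e-07) in 3 of 3 count tables. let-7g-5p fell by 2.67 ± 0.60 (adjusted p = 0.0057), and the Sfmbt2 member miR-669c-5p fell (adjusted p = 0.00476, 31.8 ± 55.2 against 3980 ± 2670 CPM, with counts in 1 of 3 OVA-lung Th2 libraries, so no size is given). These calls held with each library left out, as did that of miR-126a-3p (5.78 ± 1.15, 0.0655 ± 0.0493% against 0.000862 ± 0.00137% of the counts). Those of let-7g-5p and miR-126a-3p did not hold under every alternative with the block. The other arm, miR-126a-5p, lay below 0 in the blocked fit. miR-146a-5p rose as well (2.03 ± 0.58, adjusted p = 0.0292, 16200 ± 3630 against 2730 ± 1930 CPM). The call was lost without any 1 CD4 library or OVA-lung Th2 library 3 (1.53 to 2.30). miR-155-5p did not pass (3.81 ± 1.36, adjusted p = 0.0923).

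Of the microRNAs known to rise in activated T cells, 3 of 20 were higher in OVA-lung Th2 (7 adjusted over the list alone, adjusted p = 1.37e-05, and adjusted p = 0.0494 with an estimated correlation). Of the Sfmbt2 locus 5 of 36 fell (11 adjusted over the list alone, adjusted p = 1.72e-09, and adjusted p = 0.0494 with an estimated correlation), with a median of −4.32, or −3.09 with members at 0 counts in 1 group set at the floor. Of the clusters of miR-23, miR-27 and miR-24, 3 of 12 rose (4 adjusted over the list alone, adjusted p = 0.0192, then adjusted p = 0.256 with an estimated correlation). They were miR-27a-3p (2.56 ± 0.67, lost without CD4 library 1, 2 or 4, 1.77 to 3.06), miR-27a-5p (5.47 ± 1.40, lost without CD4 library 2, 4.73 to 6.31) and miR-24-2-5p (adjusted p = 0.0195, 998 ± 325 against 29.4 ± 35.2 CPM, with 0 counts in 2 of 4 CD4 libraries), lost without CD4 library 2, 3 or 4. Of the miR-29 family 1 of 5 fell, miR-29a-3p (−2.04 ± 0.51, lost without OVA-lung Th2 library 2 or 3, −2.80 to −1.71). The Dlk1-Dio3 list had 2 of 17 higher and 14 adjusted over the list alone (adjusted p = 1.68e-05, then adjusted p = 0.426 with an estimated correlation). But 1 library carried it: OVA-lung Th2 library 2 held 5270 CPM of the 74 entries of the list, tested or not, and libraries 1 and 3 held 0. Its miR-379-5p stood at 584 CPM in that library and at 0 in the other OVA-lung Th2 and all CD4 libraries.

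Of the markers of other cells in OVA-lung Th2, the erythroid list had 1 of 6 members higher (6 adjusted over the list alone, adjusted p = 0.0342, then adjusted p = 0.509 with an estimated correlation). The mesenchymal list had 0 of 8 (5 adjusted over the list alone, adjusted p = 0.0121, then adjusted p = 0.377 with an estimated correlation), and library 2 stood apart, with 7570 CPM of these microRNAs (2059 counts) beside 12 and 42 counts in libraries 1 and 3. The list of liver or muscle had 1 of 2, miR-1a-3p, for which library 2 held 4310 CPM and libraries 1 and 3 held 0. In all 11 microRNAs rose and 11 fell with the block (16 and 7 with size factors, 10 and 7 with library totals). Without it edgeR called 0, with 66 at an unadjusted p below 0.05, DESeq2 called 19 higher and 9 lower, and limma on the deposited RPM 4 higher and 6 lower. The balance turned with the library left out. It was 6 and 18, 3 and 16, 6 and 8, and 5 and 25 without CD4 libraries 1 to 4, and 19 and 5, 9 and 7, and 9 and 2 without OVA-lung Th2 libraries 1 to 3. The blocked count of 22 was 14 without CD4 library 3 and 11 without OVA-lung Th2 library 3. The T cells differ in organ and genotype as well, since the OVA-lung Th2 came from lungs of Il4 reporter mice.

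In Th2 cells made in culture miR-150-5p fell from 54300 ± 50200 CPM in CD4 T cells (n = 4) to 447 ± 441 CPM (n = 4), by −6.11 ± 0.66 log2 (adjusted p = 3.2e-09). miR-181a-5p fell from 20700 ± 11000 to 598 ± 414 CPM (−4.27 ± 0.70, adjusted p = 2.62e-05) and let-7b-5p, of a family that restrains growth, by −2.61 ± 0.59 (adjusted p = 0.00212). miR-21a-5p rose to 500000 ± 234000 CPM (4.36 ± 0.50, adjusted p = 1.36e-08), and the hypoxia-induced miR-210-3p to 0.994 ± 0.845% from 0.0214 ± 0.0231% of the counts (5.97 ± 0.94, adjusted p = 1.43e-05). miR-182-5p, which IL-2 induces in helper T cells, and miR-183-5p of the same cluster rose by 4.83 ± 0.95 and 5.62 ± 1.09 (adjusted p = 0.000443 each). Each was on 1 side in 4 of 4 count tables and kept its call with each library left out and under both other scalings. miR-155-5p did not pass (3.90 ± 1.32, adjusted p = 0.0576). miR-146a-5p was lower, against its direction in OVA-lung Th2 (−1.58 ± 0.53, adjusted p = 0.0433), in 3 of 4 tables. That call was lost without CD4 library 1, 2 or 4 or cultured Th2 library 1, 2 or 4 (−1.95 to −1.31).

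Of the 12 microRNAs known to be high in resting lymphocytes, 6 fell in cultured Th2 (7 adjusted over the list alone, adjusted p = 0.000332, then adjusted p = 0.113 with an estimated correlation). Of those known to rise in activated T cells 5 of 20 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.000167, then adjusted p = 0.0683 with an estimated correlation). The clusters of miR-23, miR-27 and miR-24 had 6 of 12 higher (9 adjusted over the list alone, adjusted p = 0.00191, then adjusted p = 0.113 with an estimated correlation), with miR-24-3p at 1.90 ± 0.42 and miR-27a-5p at 4.72 ± 1.27. The miR-181 family had 1 of 6 lower (3 adjusted over the list alone, adjusted p = 0.0159, then adjusted p = 0.348 with an estimated correlation). The Sfmbt2 locus had 3 of 36 lower, 0 adjusted over the list alone, and 35 of 36 below 0 (adjusted p = 5.12e-08, then adjusted p = 0.0661 with an estimated correlation). Of the miR-17-92 cluster 1 of 12 rose, miR-17-5p (2.06 ± 0.61), lost without CD4 library 1, 3 or 4 or cultured Th2 library 1 or 4 (1.53 to 2.57).

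The block gave 33 higher and 17 lower in cultured Th2 (43 and 11 with size factors, 11 and 24 with library totals). The fit without it gave 2 and 2: miR-21a-5p (4.72), miR-210-3p (5.93), miR-150-5p (−6.47) and miR-181a-5p (−4.41). The blocked count of 50 was 22, 23, 27 and 20 without CD4 libraries 1, 2, 3 and 4, and 27, 32, 32 and 20 without cultured Th2 libraries 1, 2, 3 and 4. Without CD4 library 3 or cultured Th2 library 1 it was 13 higher and 14 lower.

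Across lineages, miR-21a-5p and miR-146a-5p were both higher in IL-33 ILC2 and in OVA-lung Th2, against 0.06 shared by chance (Fisher exact one-sided p = 0.000748). Chance was not excluded for the calls of IL-33 ILC2 themselves. For the cultured cells 5 were shared among those higher (miR-21a-5p, miR-21a-3p, miR-98-5p, miR-7a-5p and miR-1983, against 1.20 by chance) and 2 among those lower (miR-150-5p and miR-150-3p, against 0.13 by chance). As arms of the same hairpin are not independent, no p is given for these. Without the block 0 were shared in vivo and 1 in culture, miR-21a-5p (Fisher exact one-sided p = 0.00521). Both Fisher p-values take the calls of the 2 lineages as independent. The calls come from 1 fit that shares its estimate of spread per microRNA, so these p-values cannot be taken at face value. Between IL-33 ILC2 and cultured ILC2, which share their controls, 2 were higher in both, against 0.07 by chance and 0.04 on average (highest 1) in simulations without effect. With the controls split, 0.5 were shared on average (0 to 1). The fold changes of those comparisons had r = 0.32 across microRNAs, which are not independent replicates, against 0.52 simulated, and a covariance of 2.30 against 2.49.

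The change in culture differed between the lineages by test for 3 microRNAs with the block. The signed difference, ILC2 minus Th2, was above 0 for 2 and below 0 for 1 (3 and 8 with size factors, 2 and 3 with library totals). miR-146a-5p rose in ILC2 and not in Th2 (difference 5.00 ± 0.76, adjusted p = 2.36e-05). miR-150-5p, already lower in lung ILC2 than in CD4 T cells, fell less in ILC2 (4.02 ± 0.79, adjusted p = 0.00105). miR-126a-3p fell in ILC2 while it rose in Th2 (−8.20 ± 1.48, adjusted p = 0.000338). Its other arm, miR-126a-5p, did not follow and lay below 0 in cultured Th2 against CD4 T cells in the blocked fit. The 3 calls held with each library left out and under each blocked alternative. But 4 of 100 splits of these libraries gave as many as 3, among them 3 of the 9 that part as many same-number pairs, so chance cannot be excluded for this count. For miR-21a-5p the difference was −0.58 ± 0.61 (adjusted p = 0.755). The cultures also differ in length (10 days for ILC2, 5 for Th2) and in cytokines, so lineage cannot be told apart from these. In vivo 14 differed with the block, 10 above and 4 below 0 (4 and 8 with size factors, 6 and 9 with library totals). The T cell side of this difference also changes organ and genotype, so a differing response to activation cannot be told apart from these. The smallest adjusted p, 0.00636, was that of 3 microRNAs. They were miR-669c-5p (counts in 1 of 3 OVA-lung Th2 libraries, lost without OVA-lung Th2 library 3), miR-126a-3p (−6.72 ± 1.48, lost without lung ILC2 library 2, −7.64 to −5.59) and miR-379-5p, whose counts in OVA-lung Th2 all lie in library 2. miR-146a-5p did not differ in vivo by test (0.22 ± 0.77, adjusted p = 0.903).

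Without the block edgeR called 0 differences in vivo, with 64 at an unadjusted p below 0.05 (DESeq2 4 and 7, limma on the deposited RPM 1), and 0 in culture, with 21 (DESeq2 1 and 5, limma 0). The blocked in vivo count of 14 was 7 without lung ILC2 library 4, 28 and 9 without IL-33 ILC2 libraries 2 and 3, 25 without CD4 library 4, and 7 (1 and 6), 8 (6 and 2) and 5 (0 and 5) without OVA-lung Th2 libraries 1, 2 and 3. That of 3 in culture was 5 without lung ILC2 library 1 and 6 without cultured Th2 library 1.

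Set directly against each other, IL-33 ILC2 held more miR-146b-5p than OVA-lung Th2 (4.62 ± 0.81 log2, adjusted p = 0.000224, 1.17 ± 1% of the counts, n = 4, against 0.0543 ± 0.0468%, n = 3). It also held more miR-99b-5p (3.00 ± 0.67, adjusted p = 0.00483) and more miR-151-3p, from an intron of Ptk2 (5.35 ± 1.08, adjusted p = 0.00166). It held less miR-150-5p (−3.78 ± 0.62, adjusted p = 9.93e-05, 2350 ± 3650 against 29400 ± 24100 CPM). These 4 calls, each on 1 side in 3 of 3 count tables, held with each library left out. miR-21a-5p was lower in IL-33 ILC2 (−2.22 ± 0.50, adjusted p = 0.00488). The call was lost without IL-33 ILC2 library 2 or 4 or OVA-lung Th2 library 1 (−2.79 to −1.36). Of the miR-17-92 cluster 1 of 12 was lower (4 adjusted over the list alone, adjusted p = 0.0241, then adjusted p = 0.256 with an estimated correlation). It was miR-19b-3p (−3.18 ± 0.92), lost without any 1 IL-33 ILC2 library or OVA-lung Th2 library 1 (−4.13 to −0.64). The Dlk1-Dio3 list had 0 of 17 past the threshold and 3 lower adjusted over the list alone (adjusted p = 0.00154, lower, then adjusted p = 0.57 with an estimated correlation). Of OVA-lung Th2, library 2 held 5270 CPM of the 74 entries of this list, tested or not, and libraries 1 and 3 held 0. With the block 7 were higher and 6 lower (3 and 16 with size factors, 7 and 6 with library totals). Without it edgeR called 0, with 62 at an unadjusted p below 0.05 (DESeq2 6 and 13, limma on the deposited RPM 1). The blocked count of 13 was 12 (11 and 1), 6 and 5 without IL-33 ILC2 libraries 2, 3 and 4, and 24 (11 and 13) and 25 (10 and 15) without OVA-lung Th2 libraries 1 and 2.

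Cultured ILC2 and cultured Th2 differed in miR-146a-5p, at 37100 ± 18500 CPM (n = 4) against 783 ± 537 CPM (n = 4), 5.43 ± 0.61 log2 higher in ILC2 (adjusted p = 1.19e-08 with the block and 0.00617 without). Also higher in ILC2 were miR-99b-5p (3.85 ± 0.62, adjusted p = 3.9e-05), miR-146b-5p (3.37 ± 0.66, adjusted p = 0.000641) and the Dlk1-Dio3 member miR-541-5p (adjusted p = 0.000486, 304 ± 302 against 0.348 ± 0.696 CPM, with counts in 1 of 4 cultured Th2 libraries). Lower in ILC2 were miR-27b-3p (−3.24 ± 0.62, adjusted p = 0.000486), miR-210-3p (−3.34 ± 0.82, adjusted p = 0.0072) and miR-17-5p (−2.59 ± 0.62, adjusted p = 0.00658). These 7 were on 1 side in 4 of 4 count tables and kept their calls with each library left out and under every alternative with the block. The cultures differ in length and cytokines too, so lineage cannot be told apart from these here.

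Of the Dlk1-Dio3 locus 12 of 17 members were higher in cultured ILC2 than in cultured Th2, 16 adjusted over the list alone with and without the block (adjusted p = 6.96e-15, then adjusted p = 0.111 with an estimated correlation). All 17 lay above 0, with a median of 7.56 (7.57 with members at 0 counts in 1 group set at the floor). Entries high in cultured ILC2 pass the filter more readily, so member counts, median and list test lean towards cultured ILC2. The sum over all 74 entries, tested or not, was higher in 4 of 4 count tables (mean 8.09, SD 1.94 log2). The paralog clusters of miR-17-92 had 2 of 11 lower (2 adjusted over the list alone, adjusted p = 0.0134, then adjusted p = 0.377 with an estimated correlation). The resting lymphocyte list had 4 of 12 lower (5 adjusted over the list alone, adjusted p = 0.0284, then adjusted p = 0.377 with an estimated correlation). The erythroid list had 2 of 6 higher, adjusted over the list alone also 2 (adjusted p = 0.0168, then adjusted p = 0.426 with an estimated correlation). The mesenchymal list had 1 of 8 higher (2 adjusted over the list alone, adjusted p = 0.101). It was miR-145a-3p (adjusted p = 0.0376, 8.42 ± 9.21 CPM against 0 counts in the 4 cultured Th2 libraries), lost without cultured ILC2 library 1 or 3 or any 1 cultured Th2 library. With the block 27 microRNAs were higher and 21 lower (18 and 24 with size factors, 34 and 11 with library totals), and without it 1 and 0. The blocked count of 48 was 21, 31, 22 and 18 without cultured ILC2 libraries 1, 2, 3 and 4, and 28, 28 and 16 without cultured Th2 libraries 1, 2 and 4. It was 8 higher and 10 lower without cultured ILC2 library 4, 11 and 17 without cultured Th2 library 2, and 24 and 10 without cultured Th2 library 3.

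**Figure D2:**
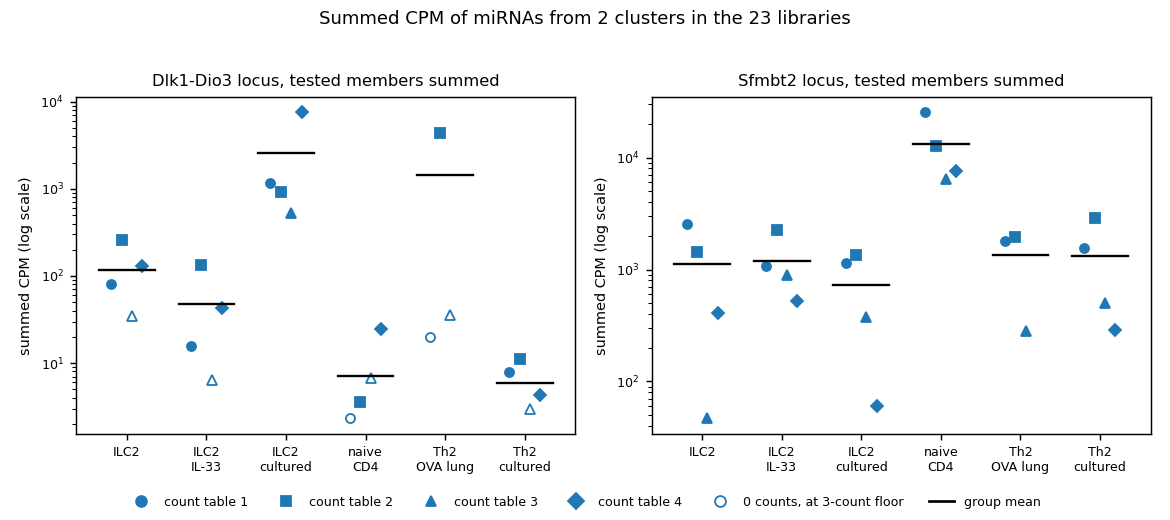
Summed CPM of the tested Dlk1-Dio3 and Sfmbt2 members in each library on a log axis, by group and count table, with open symbols for libraries at 0 counts drawn at a floor of 3 counts. Summed over all entries of each list, tested or not, Dlk1-Dio3 was higher in cultured ILC2 than in lung ILC2 in 4 of 4 count tables. Sfmbt2, summed in the same way, was lower in lung ILC2 than in CD4 T cells in 4 of 4.

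Markers of other cells were named by rule in every population. Endothelial miR-126a-3p held 0.783 ± 0.857%, 0.186 ± 0.167% and 0.0199 ± 0.0178% of the counts in lung, IL-33 and cultured ILC2. In CD4 T cells, OVA-lung Th2 and cultured Th2 it held 0.000862 ± 0.00137%, 0.0655 ± 0.0493% and 0.0108 ± 0.0118%. In the same order, mesenchymal miR-143-3p stood at 6130 ± 2770, 870 ± 768, 368 ± 554, 46.2 ± 52.2, 809 ± 1140 and 36.9 ± 68.9 CPM. Erythroid miR-451a stood at 2570 ± 4510, 620 ± 1030, 338 ± 305, 580 ± 1090, 2470 ± 2060 and 475 ± 915 CPM. Myeloid miR-223-3p held 0.0286 ± 0.0459%, 0.00361 ± 0.00388%, 0.00096 ± 0.00111%, 0.0199 ± 0.0348%, 0.038 ± 0.0648% and 0.00168 ± 0.00251% of the counts. Epithelial miR-200b-3p held 0.0109 ± 0.0187%, 0.00588 ± 0.0089%, 0.00273 ± 0.0032%, 0.0166 ± 0.0132%, 0.00502 ± 0.0087% and 0.00656 ± 0.00385%. Hepatic miR-122-5p held 0.00364 ± 0.00437%, 0.00268 ± 0.00535%, 0.0123 ± 0.0111%, 0.0127 ± 0.0232%, 0.0318 ± 0.0228% and 0.0747 ± 0.143%. The T cell regulator miR-155-5p, in the same order, stood at 427 ± 488, 1360 ± 1680, 6070 ± 9490, 514 ± 593, 6100 ± 2210 and 2830 ± 2450 CPM.

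How much of a change these libraries could show was tested on simulated counts with known changes. The changed microRNAs were drawn from all 384, of which 310 to 339 per comparison passed the filter in the simulated counts. Those that did not pass count as missed, so recovery among the microRNAs tested was higher than the shares given. With the block, changes of 4-fold and 16-fold were recovered in 6.4% and 31.8% of cases for lung ILC2 against CD4 T cells, 6.8% and 35.2% for cultured against lung ILC2, 7% and 30.4% for IL-33 against lung ILC2. They were recovered in 3.8% and 28.4% for OVA-lung Th2 and 7% and 37.4% for cultured Th2 against CD4 T cells. The values were 4.8% and 26.6% for IL-33 ILC2 against OVA-lung Th2, 6% and 35% for the cultured pair, 1% and 15.4% for the difference between lineages in vivo, and 1% and 14.8% for that in culture. Without the block at most 9.8% of 16-fold changes were recovered in any comparison. A microRNA without a call cannot be read as unchanged.

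The microRNAs that led these comparisons lie at known loci of GRCm38. Mir21a lies on chromosome 11 (86584067 to 86584158) in an exon of Vmp1, Mir126a on chromosome 2 (26591357 to 26591429) in an exon of Egfl7. Mir150 lies on chromosome 7 (45121757 to 45121821) outside annotated hosts and Mir146b on chromosome 19 (46342762 to 46342870) in an intron of Mfsd13a. Mir99b lies on chromosome 17 (17830188 to 17830257) in an intron of Spaca6. Mir23a, Mir27a and Mir24-2 lie together on chromosome 8 (84208518 to 84208921). The 17 tested Dlk1-Dio3 members span 109590447 to 109743795 of chromosome 12, and 34 of the Sfmbt2 entries 10466944 to 10517164 of chromosome 2.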

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

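Written before the data were examined were the tests of depth and of hairpin arms, and the counts of other splits except those of IL-33 against lung ILC2 and of the difference between lineages in culture. The other tests were chosen after the results were seen.

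The count tables differ in microRNA make-up: count table took a median of 31.98% of the variance of log2 CPM over 204 microRNAs, beside 32.82% for group, and 180 of the 204 range over 4-fold between tables. With every library thinned to 84918 counts and scaled by its total instead of TMM, the share of the table was 39.06%. For the deposited RPM, also scaled by totals but not thinned, it was 37.34%. That the share did not fall at equal depth argues against depth as the cause. The 5p and 3p arms of 38 hairpins did not shift together detectably between the fourth and the first table (r = 0.06, 95% interval −0.23 to 0.37, permutation p = 0.703), while they moved together between cultured Th2 and CD4 T cells (r = 0.69, 0.48 to 0.83). This is consistent with a difference in library preparation that acts on single mature sequences. It stays open whether animals or days differed with the tables.

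Dlk1-Dio3 microRNAs were higher in cultured than in lung ILC2: the summed list was over 2-fold higher in 4 of 4 count tables (19.4-fold, 3.94-fold, at least 15.8-fold with 0 counts in lung ILC2 set at 3, and 61.5-fold), which argues against a single library. The share of the counts outside the 10 most abundant microRNAs of each library did not rise with it (highest fold 0.755). That share was already 32.6% to 51.2% in lung ILC2, so it could not have risen as far as the test required. The test could therefore not decide whether a few microRNAs taking most of the counts was the cause. The values show only that the other microRNAs held a smaller share in culture. The mesenchymal list changed by −1.90 ± 0.99 log2 (mean and SE over 8 members) where the summed Dlk1-Dio3 list rose by 4.04 ± 0.81 (mean and SE over 4 tables). Dlk1-Dio3 counts were at most 0.027 times those of the mesenchymal list in lung ILC2 and 2.98 to 7.88 times those in cultured ILC2, which argues against RNA of mesenchymal cells with the make-up seen in the lung libraries. RNA of cells with more Dlk1-Dio3 than mesenchymal microRNAs and a change of the ILC2 themselves in culture stay open, untested, as does any source of the difference from cultured Th2.

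miR-126a and miR-143 were higher in lung ILC2 than in CD4 T cells. A lower purity that raises all other cells alike is argued against by the excess of miR-126a-3p over myeloid miR-223-3p (9.41 ± 1.89 log2). A lower purity that raises only some cell types stays open. All 8 mesenchymal (median 4.06) and all 6 erythroid members (median 3.50) lay above CD4 T cells with the block. Of these, 3 and 2 had 0 counts in 1 group, and with those set at a floor of 3 counts the medians were 2.98 and 3.50. miR-199a-3p and miR-199b-3p, and miR-486a-5p and miR-486b-5p, have the same counts, so the members are not all separate measurements. The epithelial median was −1.39 and myeloid miR-223-3p stood at −0.69. RNA of endothelial cells, which the sort for CD45 would remove, may account for part of it and could be neither shown nor excluded. In cultured Th2 miR-126a-3p was also 4.24 ± 1.05 above CD4 T cells. To argue against endothelial RNA the lower bound of this value, and not the value alone, had to exceed 4.36, which it did not. The test used miR-126a-3p alone. Its other arm, miR-126a-5p, lay below 0 in cultured Th2 against CD4 T cells in the same fit. The endothelial list held 0.878 ± 0.943% of the counts in lung ILC2 and 0.00894 ± 0.0153% in CD4 T cells. A common source of both microRNAs could not be told either, as their changes in culture differed by −0.22 ± 2.17. Expression by ILC2 themselves and the difference in tissue stay open, untested.

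Other splits of the same libraries were refitted to see whether chance can give as many calls. With the block, as many or more calls came from 2 of 35 splits for IL-33 against lung ILC2 (real 2, highest other 3), where chance cannot be excluded. Over all splits only the real split, 1 of 35, gave as many in the other pairs of groups. These were cultured against lung ILC2 (17, highest other 1), and OVA-lung Th2 (22, highest other 2) and cultured Th2 (50, highest other 1) against CD4 T cells. The rest were lung ILC2 against CD4 T cells (48, highest other 2), IL-33 ILC2 against OVA-lung Th2 (13, highest other 4) and the cultured pair (48, highest other 2). Most other splits leave more libraries of the same number, and so of the same count table, together. The 8 splits that part as many same-number pairs are too few for a share under 0.05, so the splits do not exclude chance. Among these 8 the highest others gave 0, 0, 1, 1, 2, 0 and 0, in the order of IL-33 and cultured against lung ILC2, OVA-lung and cultured Th2 against CD4 T cells, lung ILC2 against CD4 T cells, and the in vivo and cultured pairs. For the difference between lineages in vivo only the real split, 1 of 100, gave as many (14, highest other 9). The 6 that part as many pairs are too few for a share under 0.05 (highest other 9). These splits shuffle the lineage labels separately among the activated and among the resting libraries. A difference between the lineages themselves can so enter the change tested, and the splits cannot decide whether chance gave the count. For that in culture 4 of 100 gave as many (3, highest other 116), as did 3 of the 9 that part as many pairs. Chance is not excluded, and the count of 116 may come from the mixing of lineages in such splits, which was not tested. Without the block, a real count of 0 is matched by every split and decides nothing. This holds for IL-33 ILC2 against lung ILC2 (35 of 35, highest other 1), OVA-lung Th2 against CD4 T cells (35 of 35, highest other 1), IL-33 ILC2 against OVA-lung Th2 (35 of 35, highest other 0) and both differences between lineages (100 of 100, highest others 3 and 44). Chance could not be excluded with 2 of 35 for cultured against lung ILC2 (1, highest other 1). Over all splits only the real split, 1 of 35, gave as many for cultured Th2 (4, highest other 0) and lung ILC2 (6, highest other 1) against CD4 T cells and for the cultured pair (1, highest other 0). The 8 that part as many pairs are again too few for a share under 0.05, so chance is not excluded here either.

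Single libraries stood far from the rest of their group in 19 of 340 groups (68 microRNAs in 5 groups of 4), where chance marks about 1 in 20 groups. Values are TMM-scaled log2 CPM with the range of the other libraries. In CD4 T cells these were let-7b-5p in library 1 (15.79 against 14.40 to 14.57), miR-22-3p in library 3 (9.37 against 10.27 to 10.40), and in library 4 miR-140-3p (16.72 against 13.29 to 13.55) and miR-29a-3p (13.65 against 16.19 to 16.29). In lung ILC2 they were miR-92a-3p in library 1 (9.37 against 13.85 to 14.73), miR-200a-3p in library 2 (7.16 against 0.33), miR-27a-5p (0.33 against 8.66 to 9.34) and miR-669c-5p (0.33 against 7.71 to 7.99) in library 3, and miR-744-5p in library 4 (12.28 against 11.20 to 11.26). In IL-33 ILC2 they were miR-122-5p (7.26 against 0.33) and miR-151-5p (11.17 against 9.67 to 9.88) in library 1 and miR-27a-5p in library 2 (8.96 against 11.02 to 11.25). In cultured ILC2 they were miR-200a-3p (4.35 against 5.26 to 5.40) and miR-429-3p (3.27 against 0.33) in library 2, and miR-142a-5p (10.77 against 13.76 to 14.17) and miR-22-3p (12.23 against 13.54 to 13.70) in library 4. In cultured Th2 they were miR-92a-3p in library 1 (12.95 against 15.22 to 15.53), and miR-183-5p (15.02 against 11.06 to 11.28) and miR-296-3p (13.67 against 10.25 to 10.80) in library 4. A value of 0.33 is that of a library with 0 counts.

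The in vivo T cell groups differ in organ and genotype too, so a differing response to activation cannot be told apart from these there. In culture the same holds for the length of culture and the cytokines, which differ between ILC2 and Th2. The test of the difference between lineages with the block marked 17 results. In vivo these were let-7g-5p (2.76 ± 0.76, adjusted p = 0.03), miR-125a-3p (14.93 ± 4.16, adjusted p = 0.0314), miR-126a-3p (−6.72 ± 1.48, adjusted p = 0.00636), miR-128-3p (5.76 ± 1.65, adjusted p = 0.0328), miR-15b-5p (4.11 ± 1.12, adjusted p = 0.0298), miR-297a-5p (14.00 ± 3.72, adjusted p = 0.0277) and miR-29a-3p (2.34 ± 0.66, adjusted p = 0.0318). The others in vivo were miR-300-3p (−17.35 ± 4.57, adjusted p = 0.0288), miR-379-5p (−15.41 ± 3.38, adjusted p = 0.00636), miR-451a (−6.62 ± 1.94, adjusted p = 0.0391), miR-467a-5p (8.10 ± 2.05) and miR-467b-5p (8.02 ± 2.06, adjusted p = 0.0265 each), miR-669c-5p (8.92 ± 1.94, adjusted p = 0.00636) and miR-669o-5p (17.27 ± 4.54, adjusted p = 0.0277). Values beyond 10 on the log2 scale, and those of miR-467a-5p, miR-467b-5p and miR-669c-5p (counts in 1 of 3 OVA-lung Th2 libraries), rest on groups in which 2 or more libraries had 0 counts and give no size, and in OVA-lung Th2 miR-300-3p (287 CPM) and miR-379-5p (584 CPM) were seen in library 2 alone. In culture they were miR-126a-3p (−8.20 ± 1.48, adjusted p = 0.000338), miR-146a-5p (5.00 ± 0.76, adjusted p = 2.36e-05) and miR-150-5p (4.02 ± 0.79, adjusted p = 0.00105).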

How the results depend on the processing

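Alternatives with the newer quasi-likelihood method, and all refits of the block other than that with size factors, were chosen after seeing the data. Counts are calls at an adjusted p below 0.05, in the order cultured against lung ILC2, OVA-lung Th2, cultured Th2 and lung ILC2 against CD4 T cells, IL-33 ILC2 against OVA-lung Th2, the cultured pair, and the differences between lineages in vivo and in culture. IL-33 against lung ILC2 is named apart. Where a count moved, the cause was not tested, except that fits of fewer groups, libraries or microRNAs hold less data. The replicate block gave calls to named results that had none, in the same direction, and took 0 calls from a named result.

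From 1, 0, 4, 6, 0, 1, 0 and 0 calls without a block, the replicate block gave 17, 22, 50, 48, 13, 48, 14 and 3, with 2 for IL-33 against lung ILC2. The replicate block with DESeq2 size factors gave 16, 23, 54, 25, 19, 42, 12 and 11, with 1 for IL-33. The DESeq2 test without a block gave 5, 28, 32, 31, 19, 25, 11 and 6, with 3 for IL-33. Shared calls were 0 in vivo, 1 in culture and 0 between the ILC2 comparisons. They were 2, 7 and 2 with the replicate block, 1, 9 and 1 with the replicate block and DESeq2 size factors, and 1 in vivo and 1 between the ILC2 comparisons with the DESeq2 test. Under the DESeq2 size factors cultured against lung ILC2 gave 0, the difference in culture 1 and the shared calls in culture 0. Library totals only gave 0 for cultured against lung ILC2, 5 for OVA-lung Th2, 12 for the cultured pair, 3 and 1 for the differences and 0 shared in culture. No low-count filter gave 0 for cultured against lung ILC2, 2 for lung ILC2 against CD4 T cells, 0 for the cultured pair and 0 shared in culture. With only the groups compared it was 0 for cultured against lung ILC2, 2 for OVA-lung Th2, 1 for cultured Th2, 3 for the cultured pair and 0 shared in culture. limma on deposited RPM gave 3 for cultured against lung ILC2, 10 for OVA-lung Th2, 1 for IL-33 ILC2 against OVA-lung Th2, 12 for the cultured pair, 1 for the difference in vivo and 0 shared in culture. With only miRNAs in all 4 tables it was 0 for cultured against lung ILC2 and 0 shared in culture. The newer quasi-likelihood method gave 4, 15, 25 and 23 for the first 4 comparisons, 45 for the cultured pair and 2 for each difference.

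From the blocked counts, the replicate block with library totals only gave 1 for IL-33, 26 for lung ILC2 against CD4 T cells and 5 for the difference in culture. The replicate block in the DESeq2 test gave 42, 55 and 83 for the first 3 comparisons, 56 for IL-33 ILC2 against OVA-lung Th2, and 36 and 30 for the differences. The replicate block with the newer quasi-likelihood method gave 60, 61, 118, 98, 37, 89, 26 and 20. The replicate block with 10 counts in 12 libraries gave 1 for IL-33, 8 for cultured against lung ILC2, 20 for IL-33 ILC2 against OVA-lung Th2, 24 for the cultured pair and 9 for the difference in culture. The replicate block with only the groups compared gave 0 for IL-33, 11 for OVA-lung Th2, 8 for IL-33 ILC2 against OVA-lung Th2, 22 for the cultured pair, and 2 and 5 for the differences. The replicate block without the libraries under 100000 counts gave 0 for IL-33, 9 for cultured against lung ILC2, 30 for lung ILC2 against CD4 T cells, 8 for IL-33 ILC2 against OVA-lung Th2, and 6 and 7 for the differences.

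Of 105 list tests, 30 passed without a block and 0 with an estimated correlation, 33 with the replicate block and 3 of these with an estimated correlation. The value of miR-21a-5p for the difference in vivo, 0.19 without a block and without a call, turned to −2.71 (adjusted p = 0.00229) under the replicate block with DESeq2 size factors. With each library left out, the unblocked counts ranged 0 to 1 for cultured against lung ILC2, 0 to 4 for OVA-lung Th2, 1 to 8 for cultured Th2, 1 to 6 for lung ILC2 against CD4 T cells, 0 to 0 for IL-33 ILC2 against OVA-lung Th2, 0 to 4 for the cultured pair, 0 to 2 and 0 to 1 for the differences, and 0 to 1 for IL-33. Shared calls ranged 0 to 0 in vivo, 0 to 1 in culture and 0 to 1 between the ILC2 comparisons. The blocked counts ranged 4 to 18, 11 to 30, 20 to 32, 25 to 49, 5 to 25, 16 to 34, 5 to 28 and 3 to 6 in the order above, and 0 to 3 for IL-33. In the order of the first 7 comparisons the lowest came without lung ILC2 library 4 or cultured ILC2 library 4, OVA-lung Th2 library 3, CD4 T cell library 4 or cultured Th2 library 4, lung ILC2 library 4, IL-33 ILC2 library 4, cultured Th2 library 4 and OVA-lung Th2 library 3. For IL-33 it came without lung ILC2 library 2 or IL-33 ILC2 library 4. For the difference in culture the lowest, 3, is the count with all libraries. For cultured Th2 against CD4 T cells the count of 50 fell whichever library was left out, to 27 without CD4 T cell library 3 or cultured Th2 library 1.

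Among single named microRNAs with the block, 43 lost and 19 gained a call with size factors, 49 and 14 with library totals, 22 and 81 in the DESeq2 test, 1 and 85 with the newer method, 20 and 15 with the stricter filter, 52 and 13 in fits of the groups compared, and 39 and 10 without the shallow libraries, all in the same direction. In the order given, values without a call changed sign in 36, 44, 42, 21, 14, 21 and 29 results. Without a block 89 gained and 1 lost a call in the DESeq2 test, 59 gained with the newer method, 28 gained and 4 lost with limma, 17 gained and 3 lost with library totals, and 2 gained and 4 lost with size factors, and values without a call changed sign in 34, 3, 69, 48 and 34. The shallowest libraries hold 84918 to 89680 counts, which limits what can be seen of rare microRNAs there.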

Other observations

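No test in this part was chosen after the result was seen, but miR-1a-3p was picked after its values were seen. Shares of the counts are means with SD over the libraries of a group. The let-7 family held 37.2 ± 5%, 30.4 ± 9.16% and 30.4 ± 18.9% in lung, IL-33 and cultured ILC2, and 36.6 ± 6.97%, 15.8 ± 2.86% and 15 ± 5.24% in CD4 T cells, OVA-lung Th2 and cultured Th2. The clusters of miR-23, miR-27 and miR-24 held 11.4 ± 7.32%, 12.7 ± 8.44% and 5.42 ± 4.26% in the ILC2 and 2.69 ± 0.712%, 5.89 ± 3.7% and 8 ± 6.62% in the T cells. The miR-181 family held 0.508 ± 0.277%, 0.363 ± 0.222% and 0.102 ± 0.0676%, and 2.38 ± 1.17%, 0.941 ± 0.802% and 0.123 ± 0.042%. The miR-30 family, of broad expression, held 3.97 ± 2.04%, 3.1 ± 1.68% and 1.51 ± 0.879%, and 3.16 ± 1.8%, 2.28 ± 1.6% and 0.835 ± 0.399%, with 0 of 11 members past the threshold in each comparison. The epithelial markers held 0.175 ± 0.0859%, 0.0763 ± 0.0408% and 0.0339 ± 0.0113%, and 0.0947 ± 0.0442%, 0.0941 ± 0.0706% and 0.0394 ± 0.0257%.

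The muscle microRNA miR-1a-3p stood at 1440 ± 2490 CPM in OVA-lung Th2 (n = 3), against 1.34 ± 2.68 CPM in CD4 T cells and 27.8 ± 19.3 CPM in IL-33 ILC2 (n = 4 each). The OVA-lung value rests on library 2 alone, at 4310 CPM beside 0 in libraries 1 and 3, although edgeR with the replicate block called it (adjusted p = 0.0378). In cultured ILC2 miR-1a-3p stood at 25 ± 14.1 CPM, against 0 counts in the 4 cultured Th2 libraries (adjusted p = 0.00521). miR-486a-5p and miR-486b-5p, erythroid microRNAs of the same mature sequence with identical counts here, were higher in cultured ILC2 than in cultured Th2 (5.13 ± 1.60 each, adjusted p = 0.0315). Neither was among the calls that held with each library left out and under every alternative with the block.

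Of the marker lists, with the replicate block, the myeloid list (1 tested) had 0 calls in each comparison, and 1 when adjusted over the list alone, lower in cultured than in lung ILC2. Of 2 endothelial microRNAs 1 was higher in lung ILC2, OVA-lung Th2 and cultured Th2 than in CD4 T cells, and 1 was lower in cultured than in lung ILC2, where adjusted over the list alone 2 were lower. Of 10 epithelial microRNAs 1 was higher and 1 lower in cultured Th2 than in CD4 T cells and 1 was higher in cultured ILC2 than in cultured Th2, with 0 in the other comparisons, and the same counts when adjusted over the list alone.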
